A study of Mus musculus with 17 samples.

How the data were processed

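The study sequenced bulk RNA from 17 mouse libraries: 5 brain tissue imprints of the OFC before oDASS and 6 OFC and 6 mPFC dissections after it. Per the labels, RNA was extracted with a Qiagen kit and libraries were made with SMART-Seq v4 and Nextera reagents, which do not keep the strand. The deposited tables hold raw counts per gene, 1 column per library and 25239 genes in each of 3 tables, together with a gene length in bases. The values are whole numbers with a different total in each column. The submitters' processing notes name FastQC 0.11.8 and the genome build mm10; the aligner, the counting program and the annotation are not given in the sources used here. Gene symbols were matched to the mouse RefSeq annotation of GRCm38 for positions and overlaps, and 99.2% of the identifiers matched.

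Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept with filterByExpr for the groups compared, libraries were scaled by TMM, and quasi-likelihood fits with a robust spread were tested on both sides, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are log2 values from the model; positive values are higher in perseverers, in the OFC or in the imprints. The SE printed beside a fold change is the size of the fold change divided by the square root of the F statistic and is approximate. Counts scaled to a common library size (CPM) are means over libraries with their SD after TMM scaling, except where a value is said to be of the library total. The 3 comparisons between phenotypes were each fitted within 1 table, the regions within the 12 dissections with phenotype as a term, and imprint against dissection within the 11 OFC libraries with phenotype as a term. Interactions were contrasts of 4 group means. Stage and way of collection coincide, so that neither can be tested alone.

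Gene lists for cell types, receptors, channels, synapses and stress responses (38 lists) were fixed before the data were examined, as were the comparisons, the tests, the leave-outs and most alternatives. Lists with at least 3 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Camera compares a list with all other genes. No list call of the main fit of any comparison held with an estimated correlation, which was used on the main fits only. Counts adjusted over the list alone use only the p values of its members.

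Genes were named by a rule fixed in advance: per comparison, the 10 higher and 10 lower genes with the smallest p among those past the threshold, filled up to 5 in a direction where fewer passed, and up to 2 members of each list with the smallest p (up to 4 for a list past its test). Genes without an ordinary name and a fixed list of sex marker genes were counted and not named, and not every gene the rule takes is printed. Of 167 genes checked, 9 shared at least 20% of their exon bases with another gene. Groups of libraries were also compared by exact permutation of all splits for haemoglobin share, genes detected after thinning to equal depth, gene length trend and mean marker levels. The gene length trend of a library is the Spearman correlation of each gene's deviation from its table's mean log2 expression with gene length, over genes with a mean log2 CPM above 4.

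Alternatives were DESeq2 1.42.0 with its own size factors, limma voom with quality weights, RLE and upper-quartile scaling, no low-count filter and a stricter one, a threshold of 0.1, fits of more libraries together, the replicate number as a block, fry in place of camera, and leaving out each library. Chosen after the data were seen were the stricter filter, no filter and the fit of all 17 libraries for the lists, removal of the haemoglobin genes, removal of identical-count copies, removal of the length trend of each library, library totals alone as scaling, the myelin level as a covariate and the lower or upper part of the sample code numbers as a covariate.

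The tests were checked on simulated data made from the same libraries, with 200 genes changed. With edgeR, 1.5-fold, 2-fold and 4-fold changes were recovered in 0%, 0% and 0% in the imprints, 1.54%, 53.0% and 92.3% in the OFC dissections, 5.97%, 37.3% and 83.3% in the mPFC, 28.4%, 77.3% and 92.2% between regions, 0%, 6.15% and 67.7% for the interaction with region, 0%, 11.9% and 58.5% between imprint and dissection, and 0%, 0% and 0% for the interaction with stage. False calls numbered 0, 13, 8, 4, 3, 2 and 0, among 0, 109, 92, 133, 51, 48 and 0 calls outside the raised list. DESeq2 made 13 false calls of 22 in the imprints, 29 of 176 between regions and 5 of 18 for the interaction with stage. Between regions limma made 4 of 133. A list raised by 1.5-fold was found by camera in all 7 comparisons; with an estimated correlation it was missed in the imprints (adjusted p = 0.999), the OFC dissections (0.257), the mPFC (0.057) and the interaction with stage (0.372). Beside the raised list, 1 unchanged list was called in the mPFC and 0 in the other 6 comparisons. Without a change, 0 lists were called, and 0 genes except 3 in the mPFC. Simulated genes were drawn independently of each other, unlike genes in real libraries. The list calls and the concordance on simulated data therefore do not show how these tests behave with correlated genes. A simulated length trend (Spearman correlation 0.549) was reduced to 0.0154 by its removal, and a simulated shared change gave a concordance of 0.173 (permutation p = 0.01).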

Results

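Bulk RNA was sequenced from the orbitofrontal cortex (OFC) and the medial prefrontal cortex (mPFC) of DAT-cre mice, a line that carries Cre recombinase in dopamine neurons. The mice went through oDASS, in which an animal triggers light stimulation of its own dopamine neurons, and the labels class them as perseverers (addicted) or renouncers (non-addicted). The 17 libraries fell into 6 groups. Before oDASS, brain tissue imprints of the OFC gave 3 renouncer and 2 perseverer libraries. After oDASS, dissections of the OFC gave 3 renouncer and 3 perseverer libraries, and dissections of the mPFC 3 and 3. The labels do not say whether replicates are separate animals or which libraries share an animal.

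Total counts per library were 9328876, 10662666 and 10483783 in the renouncer imprints and 8960549 and 9897780 in the perseverer imprints, in the order of their replicate numbers. OFC dissections held 20945108, 13997596 and 15334962 counts in renouncers and 17048313, 18321777 and 14618655 in perseverers. The mPFC dissections held 16072705, 12392731 and 12565460 in renouncers and 14734145, 13677451 and 17895184 in perseverers. Expression levels are given as CPM, the counts of a gene scaled to a common library size. Intervals given for a share of counts are 95% exact binomial intervals and cover counting error only.

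Haemoglobin genes, which are expressed in red blood cells, took most of the counts of 4 of the 5 imprints. The share of the 6 adult haemoglobin genes was 90.7% (interval 90.6 to 90.7) in renouncer replicate 2, 89.7% (89.7 to 89.7) in renouncer replicate 3, 85.4% (85.4 to 85.4) in perseverer replicate 1 and 90.1% (90.1 to 90.1) in perseverer replicate 2. Renouncer replicate 1 held 29.7% (29.7 to 29.8). In the 6 OFC dissections the share was 0.0569% ± 0.0178 (SD, n = 6), against 77.1% ± 26.6 (SD, n = 5) in the imprints, with every imprint above every dissection. The exact permutation test gave p = 0.00216, the smallest the 462 splits allow, and an adjusted p of 0.00303 over 28 measures. Several haemoglobin genes are near-identical copies, so their counts are given only as a sum, which may hold some reads more than once. With each near-identical pair counted once, the share was 67.6% ± 28.2 in the imprints and 0.0284% ± 0.0089 in the OFC dissections. Renouncer replicate 1 then held 17.5%. Counts outside the haemoglobin genes came to 6556052 in renouncer replicate 1 and to 995960, 1082473, 1306627 and 980536 in the other imprints. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, stood at 454 CPM of the library total in renouncer replicate 1 and at 22.1 to 52.0 in the other imprints. Ttr, the transthyretin gene of the choroid plexus, did not exceed 9.10 CPM in any OFC dissection.

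**Figure D1:**
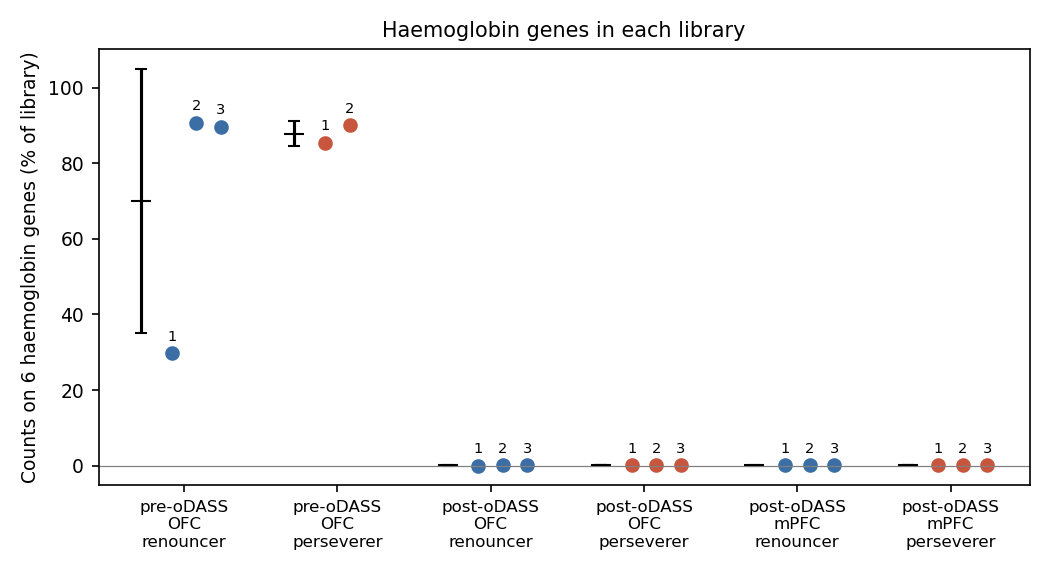
Share of counts on 6 haemoglobin genes in each of the 17 libraries, in percent of the library total, by group; points are libraries with their replicate number and black bars show the group mean ± SD. Of the imprints, 4 lie between 85.4% and 90.7% and 1 at 29.7%, and the highest dissection lies at 0.0787%.

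The first comparison asked which genes differed between perseverers and renouncers in the imprints taken before oDASS. Markers of infiltrating immune cells lay higher in the perseverer imprints, with a positive fold change in 10 of 12 measured members and a median log2 fold change of 0.89 (2 libraries against 3). Among them, Cd79a, a part of the B cell receptor, stood at 55.1 ± 5.07 CPM against 20.9 ± 18.5, a log2 fold change of 1.42 ± 0.80 (SE). By library, the mean log2 level of the immune list per library total was 3.63 ± 0.73 in perseverers and 3.54 ± 0.86 in renouncers (exact permutation p = 0.8), with the highest value, 4.53, in renouncer replicate 1, whose haemoglobin share was 29.7%. On that scale lymphocyte and erythroid genes lay higher in perseverers, by 0.98 and 0.65, and platelet and neutrophil genes lower, by -1.32 and -1.13, and none of the 4 differences passed. With 10 splits the smallest possible permutation p is 0.1, so that neither these differences nor that of the immune list could pass by permutation. The list passed its test (adjusted p = 0.00607; adjusted p = 0.891 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone. Higher genes included Lrmp, a lymphoid membrane protein gene on chromosome 6 (145111715 to 145174929, GRCm38), at a log2 fold change of 3.63 ± 1.01, Def6, a T cell signalling gene, at 2.57 ± 0.73, and Cd69, an early activation marker of lymphocytes, at 3.90 ± 1.22. On the lower side, Rapgef5, a Ras-family exchange factor, stood at -3.21 ± 0.83 and Lss, the lanosterol synthase of sterol synthesis, at -3.74 ± 1.07. None of these genes passed the threshold.

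Of 10530 genes tested in the imprints, 0 passed with edgeR (181 at an unadjusted p under 0.05, smallest adjusted p 0.99989), 0 with DESeq2 (237 unadjusted) and 0 with limma (517 unadjusted). A fit of all 17 libraries that shared 1 spread estimate called 63 genes (19 higher, 44 lower) and 0 lists. The immune list's call ended without perseverer replicate 1 (adjusted p = 0.0534), perseverer replicate 2 (0.174) or renouncer replicate 1 (0.463). Without 1 of the 2 perseverers that side holds 1 library, which is assumed to vary like the renouncers. The number of lists went from 1 of 35 to 0, 2, 2 and 6 without perseverer replicate 1, perseverer replicate 2, renouncer replicate 1 and renouncer replicate 2. On simulated changes of 4-fold in these 5 libraries the edgeR test recovered 0%.

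After oDASS, the OFC dissections of perseverers were compared with those of renouncers (3 against 3). Endothelial markers lay higher in perseverers, with 12 of 13 members positive and a median log2 fold change of 0.20. Kdr and Flt1, receptors for vascular endothelial growth factor, stood at 0.64 ± 0.24 and 0.49 ± 0.21, and Slco1a4, a transporter of brain capillaries, at 0.38 ± 0.17. The list passed its test (adjusted p = 0.00865, and adjusted p = 0.799 with an estimated correlation) and kept its call when any 1 of the 6 libraries was left out. By library, the mean log2 level of the endothelial list per library total was 4.22 ± 0.08 in perseverers and 4.01 ± 0.18 in renouncers. The exact permutation p for that difference was 0.2, where the smallest possible is 0.1. Metabotropic glutamate receptor and scaffold genes also lay higher, with 22 of 28 members positive and a median of 0.17, among them Shank1 (0.55 ± 0.23) and Dlgap4 (0.36 ± 0.18), which code for scaffolds of the postsynaptic density. That list passed as well (adjusted p = 0.00865; adjusted p = 0.799 with an estimated correlation) and was kept in all 6 leave-outs. In both lists 0 members passed over all genes and 0 adjusted over the list alone.

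Nuclear genes of oxidative phosphorylation lay lower in perseverer OFC, with 56 of 60 members negative and a median log2 fold change of -0.25. Sdhd of complex II stood at 283 ± 51.1 CPM against 369 ± 99.6, and Ndufs4 of complex I at 179 ± 41.4 against 239 ± 70.7 (SD, n = 3 each). The list passed (adjusted p = 2.12e-06; adjusted p = 0.799 with an estimated correlation), and its call ended without renouncer replicate 3 (0.629). Cytosolic ribosomal protein genes lay lower in 70 of 78 members with a median of -0.20, among them Rpl6 (-0.32 ± 0.22). Their list passed (adjusted p = 3.84e-04; adjusted p = 0.867 with an estimated correlation), ended without perseverer replicate 2 (0.346) and turned to the other direction without renouncer replicate 3 (0.629). Meningeal fibroblast markers lay lower in 13 of 14 members with a median of -0.33, among them the collagen gene Col1a1 (-1.20 ± 0.56) and the matrix gene Mgp (-1.22 ± 0.80; the sign turned without renouncer replicate 2). That list (adjusted p = 0.0479; adjusted p = 0.813 with an estimated correlation) lost its call without perseverer replicate 1 (0.402) or perseverer replicate 3 (0.13) and changed direction without renouncer replicate 2 (0.141). In these 3 lists 0 members passed over all genes and 0 adjusted over the list alone.

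Circadian clock genes, upper-layer cortical markers and astrocyte markers lay higher in perseverer OFC, with 15 of 19, 10 of 12 and 11 of 13 members positive and medians of 0.22, 0.22 and 0.13. Per2, a core clock repressor, stood at 0.43 ± 0.19, Cux2, a transcription factor of upper cortical layers, at 0.42 ± 0.16, and Slc1a2, the main glutamate transporter of astrocytes, at 0.33 ± 0.19. The adjusted p values were 0.0132, 0.0322 and 0.0479 (for each list adjusted p = 0.799 with an estimated correlation), and in the 3 lists 0 members passed over all genes and 0 adjusted over the list alone. The clock list ended without perseverer replicate 2 (0.204), perseverer replicate 3 (0.0517) or renouncer replicate 2 (0.0619). The upper-layer list ended without perseverer replicate 2 (0.821) or renouncer replicate 3 (0.0903), and the astrocyte list without perseverer replicate 3 (0.401), renouncer replicate 1 (0.158) or renouncer replicate 3 (0.32). Each of the 10 splits of the OFC dissections into 3 against 3 gave at least as many lists as the 8 of the phenotypes.

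Single genes in the OFC dissections did not pass the threshold. The smallest p values belonged to Kcnk3, a background potassium channel gene on chromosome 5 (30588170 to 30625270), at 21.9 ± 2.16 CPM in perseverers against 14.0 ± 0.725 (log2 fold change 0.64 ± 0.17), and Plce1, a phospholipase C gene, at 1.03 ± 0.28. Sfrp1, a secreted inhibitor of Wnt signalling, stood at 0.59 ± 0.17, and Npr3, the clearance receptor for natriuretic peptides, at -1.02 ± 0.28. Alas2, the haem synthesis enzyme of red cell precursors, stood at 0.98 ± 0.29 and was the 1 member of the 8 blood cell markers that passed adjusted over the list alone. Of 14621 genes, 0 passed with edgeR (377 at an unadjusted p under 0.05, smallest adjusted p 0.951), 0 with DESeq2 (420) and 0 with limma (950). On simulated data in these libraries edgeR recovered 92.3% of 4-fold, 53.0% of 2-fold and 1.54% of 1.5-fold changes.

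Longer genes tended to have higher fold changes for perseverers in the OFC dissections, with a Spearman correlation of 0.441 across 8444 genes, which are not independent replicates. The correlation was 0.286 without perseverer replicate 2 and 0.243 with the lower or upper part of the sample code numbers as a covariate. By library, the trend of expression with gene length was 0.251, 0.374 and -5.1e-04 in perseverers and 0.289, -0.360 and -0.420 in renouncers, and the group means differed by 0.372 (exact permutation p = 0.3; the smallest possible is 0.1), by 0.598 without renouncer replicate 1 and by 0.244 without renouncer replicate 3. With each library's length trend removed, 3 lists passed, of which the endothelial list (adjusted p = 0.00625) was the 1 shared with the 8 above. The other 2 were blood cell markers, higher (median 0.51, adjusted p = 1.89e-04), and GABA receptor genes, lower (median -0.14, adjusted p = 0.0419). These calls after removal were not tested with an estimated correlation. By library and before removal, blood cell markers lay at 2.94 ± 0.18 in perseverers and 2.76 ± 0.30 in renouncers (exact permutation p = 0.4). The haemoglobin share was 0.0609% ± 0.0082 and 0.0528% ± 0.0260 (exact permutation p = 0.8).

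**Figure D2:**
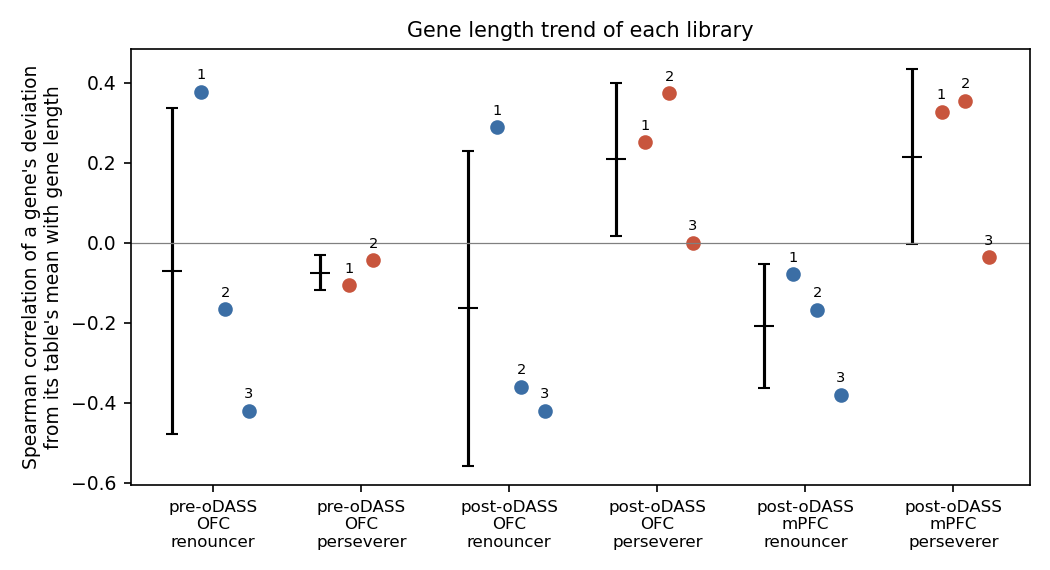
Spearman correlation, for each library, of a gene's deviation from its table's mean log2 expression with gene length; points are libraries with their replicate number and black bars show the group mean ± SD. In the mPFC the 3 perseverer libraries lie above the 3 renouncer libraries, and in the OFC dissections renouncer replicate 1 (0.289) lies among the perseverers.

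In the mPFC dissections, perseverers were again compared with renouncers (3 against 3). Markers of migrating neuroblasts and of the olfactory bulb lay higher in perseverers, with 8 of 10 members positive and a median log2 fold change of 0.81. Dcx, a microtubule protein of young neurons, stood at 6.02 ± 1.28 CPM against 3.57 ± 0.766 (log2 fold change 0.76 ± 0.37), and Dlx2, a transcription factor of interneuron precursors, at 0.86 ± 0.39. Doc2g stood at 7.55 ± 10.6 CPM against 1.94 ± 1.45, with a log2 fold change of -0.41 without perseverer replicate 3, and 63.5% of its exon bases overlap another annotated gene, so its value is uncertain. The list passed (adjusted p = 0.00912; adjusted p = 0.506 with an estimated correlation) and its call ended without perseverer replicate 3 (0.277). Meningeal fibroblast markers lay higher in 12 of 14 members with a median of 0.44, among them Dcn, a matrix proteoglycan gene (0.96 ± 0.36), and Aldh1a2, a retinoic acid synthesis gene of the meninges (1.29 ± 0.57). Their list passed (adjusted p = 0.0433; adjusted p = 0.814 with an estimated correlation) and ended without perseverer replicate 2 (0.212), perseverer replicate 3 (0.938), renouncer replicate 1 (0.133) or renouncer replicate 2 (0.403). In both lists 0 members passed over all genes and 0 adjusted over the list alone.

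Lists of synapse and ion channel genes lay higher in perseverer mPFC in 5 cases, while GABA receptor genes (median -0.06, adjusted p = 0.697) and ionotropic glutamate receptor genes (0.09, 0.425) did not pass. The median log2 fold change was 0.16 for metabotropic glutamate receptor and scaffold genes (21 of 28 positive), 0.13 for synaptic vesicle genes (25 of 33), 0.17 for spine and actin genes (18 of 25), 0.19 for voltage-gated potassium channels (19 of 25) and 0.22 for voltage-gated sodium and calcium channels (19 of 23). Examples were Shank2, a postsynaptic scaffold (0.60 ± 0.24), Syn1, a synaptic vesicle protein (717 ± 105 CPM against 501 ± 17.7; 0.52 ± 0.17), Bsn, a scaffold of the presynaptic active zone (0.60 ± 0.24), and Hcn2, a channel activated by hyperpolarisation (0.63 ± 0.29). Neurotrophin and growth factor genes (18 of 22 positive, median 0.26) and circadian clock genes (15 of 19, median 0.19) also lay higher, among them Igf1r (0.54 ± 0.21) and Per2 (0.76 ± 0.28). The adjusted p was 0.0111 for the glutamate list, 0.0433 for the growth factor list and 0.0299 for the other 5 (adjusted p = 0.506 to 0.543 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Each of the 7 calls ended when some single library was left out. The glutamate list ended without perseverer replicate 3 (0.0578) or renouncer replicate 3 (0.093), and the clock list without perseverer replicate 2 (0.239), perseverer replicate 3 (0.0578) or renouncer replicate 3 (0.202). The spine list ended without perseverer replicate 2 (0.104), renouncer replicate 1 (0.0544) or renouncer replicate 3 (0.127), and the potassium channel list without perseverer replicate 1 (0.0929), perseverer replicate 2 (0.239) or renouncer replicate 3 (0.0902). The vesicle list ended without perseverer replicate 1 (0.107), perseverer replicate 2 (0.0883), renouncer replicate 1 (0.0655) or renouncer replicate 3 (0.0591). The sodium and calcium channel list ended without perseverer replicate 1 (0.0828), perseverer replicate 2 (0.22), renouncer replicate 1 (0.0655) or renouncer replicate 2 (0.0785). The growth factor list was kept in 1 of 6 leave-outs and ended without perseverer replicate 1 (0.116), 2 (0.0883) or 3 (0.0795) and without renouncer replicate 1 (0.118) or 3 (0.138).

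Nuclear oxidative phosphorylation genes lay lower in perseverer mPFC in 57 of 60 members, with a median of -0.19, as did ribosomal protein genes in 58 of 78 (median -0.11) and inhibitory neuron markers in 11 of 14 (median -0.16). Sst, the somatostatin gene of 1 class of interneurons, stood at 318 ± 21.4 CPM against 501 ± 108.5 (log2 fold change -0.66 ± 0.19), and Vip, a peptide gene of another class, at -0.42 ± 0.18. The adjusted p values were 0.00103, 0.0433 and 0.0299 (adjusted p = 0.82, 0.913 and 0.591 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The oxidative phosphorylation list ended without perseverer replicate 2 (0.239) or renouncer replicate 3 (0.761), the inhibitory list without perseverer replicate 3 (0.368) or renouncer replicate 3 (0.272), and the ribosomal list without perseverer replicate 1 (0.731), while it turned to the other direction without perseverer replicate 2 (0.795) or renouncer replicate 3 (0.265).

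No single gene passed in the mPFC. Gcn1, a ribosome-binding regulator of the amino acid stress response on chromosome 5 (115565117 to 115622654), stood at 47.1 ± 2.17 CPM in perseverers against 23.4 ± 6.07 (log2 fold change 1.01 ± 0.22). Nos1, the neuronal nitric oxide synthase, stood at 33.9 ± 4.24 against 18.5 ± 2.37 (0.88 ± 0.20), Fat1, a large cadherin, at 1.82 ± 0.43, F3, the tissue factor of coagulation, at -0.66 ± 0.16, and Kat8, a histone acetyltransferase, at -0.68 ± 0.20. Of 14375 genes, 0 passed with edgeR (639 at an unadjusted p under 0.05, smallest adjusted p 0.943), 0 with DESeq2 (767) and 0 with limma (2151), while edgeR recovered 83.3% of simulated 4-fold and 37.3% of 2-fold changes in these libraries. The 12 lists of this comparison became 4, 7 and 5 without perseverer replicate 2, perseverer replicate 3 and renouncer replicate 3. Longer genes tended to have higher fold changes across 8511 genes (Spearman correlation 0.459). The trend by library was 0.215 ± 0.219 in perseverers and -0.209 ± 0.155 in renouncers (exact permutation p = 0.1, the smallest possible), and with it removed only the neuroblast list (adjusted p = 0.0181) and the meningeal list (0.0296) passed.

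**Figure D3:**
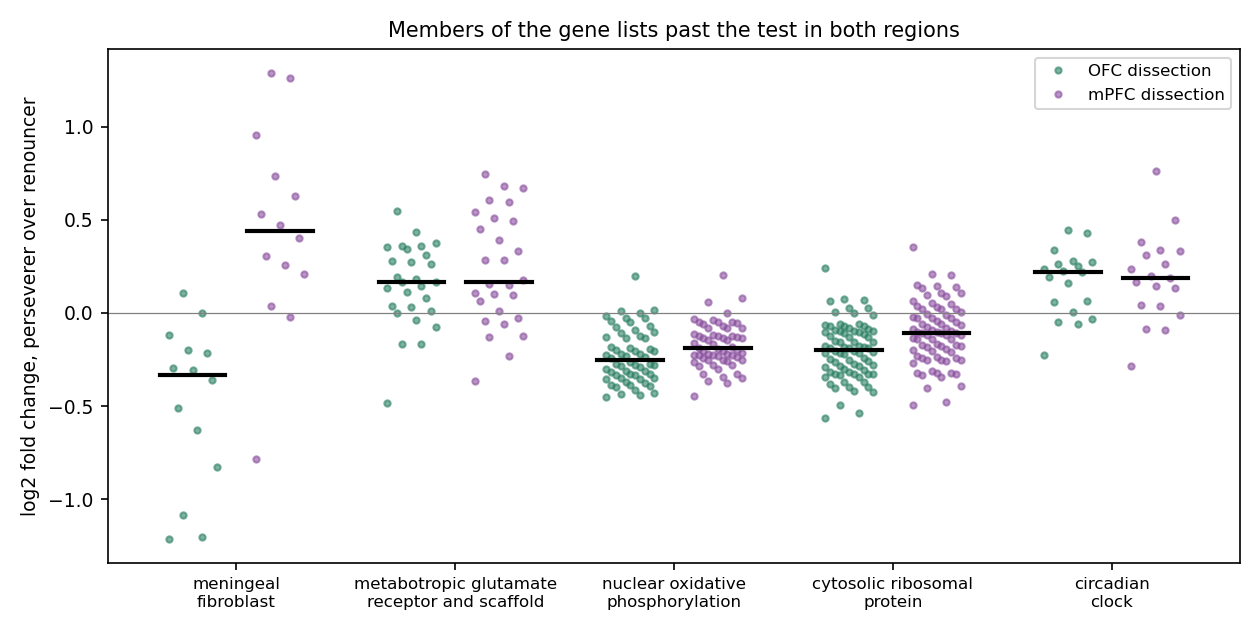
Log2 fold changes of perseverers over renouncers for the members of the 5 gene lists past their test in both regions; points are genes, green for OFC and purple for mPFC dissections, and black lines are medians. Medians share their sign in 4 lists and differ for meningeal fibroblast markers (-0.33 in the OFC, 0.44 in the mPFC).

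Fold changes between phenotypes were set side by side to ask whether the imprint showed the difference seen later and whether both regions shared it. Across 10251 genes, fold changes of the imprints and of the OFC dissections had a Pearson correlation of -0.0468 (permutation p = 0.39 over 200 relabellings of libraries) and a Spearman correlation of -0.0651 (p = 0.35). The sign turned without imprint renouncer replicate 1 (0.0303) or imprint perseverer replicate 1 (0.0103). Across 14204 genes, OFC and mPFC dissections had a Pearson correlation of 0.269 (permutation p = 0.13 over 400 relabellings) and a Spearman correlation of 0.397 (p = 0.08), with the same sign in 67.9% of genes, and neither passed the threshold. Leaving out OFC renouncer replicate 3 lowered the Pearson correlation to 0.178. Genes within a library are not independent replicates, so libraries were relabelled.

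The difference between phenotypes itself was compared between regions, as perseverer over renouncer in the OFC minus the same in the mPFC. Endothelial markers had a higher difference in the OFC in 13 of 13 members (median log2 difference 0.45), among them Esam, an adhesion protein of endothelial junctions (0.90 ± 0.33), and Kdr (0.71 ± 0.44). Meningeal fibroblast markers had a lower difference in 14 of 14 members (median -0.83), among them Dcn (-2.04 ± 1.01) and Aldh1a2 (-1.92 ± 0.76), and neuroblast markers in 8 of 10 (median -0.73), among them Dcx (-0.74 ± 0.40). The adjusted p values were 5.07e-04, 5.07e-04 and 0.00593 (adjusted p = 0.626, 0.968 and 0.626 with an estimated correlation), with 0 members past over all genes or adjusted over the list alone. The endothelial call was kept in all 12 leave-outs. The meningeal call ended without mPFC perseverer replicate 3 (0.186), mPFC renouncer replicate 2 (0.081) or OFC renouncer replicate 2 (0.538), and the neuroblast call without mPFC perseverer replicate 3 (0.286), mPFC renouncer replicate 2 (0.0792) or OFC renouncer replicate 3 (0.076).

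The lower genes with the smallest p for this difference were Gcn1 (-1.25 ± 0.26), Rrp12, a ribosome assembly gene (-1.01 ± 0.24), and Egfr, the epidermal growth factor receptor (-1.15 ± 0.28), none past the threshold. Of 15025 genes, 0 passed with edgeR (225 at an unadjusted p under 0.05), 0 with DESeq2 (287) and 0 with limma (659). The 3 lists became 5 without mPFC perseverer replicate 1, mPFC perseverer replicate 2 or mPFC renouncer replicate 1, 6 without mPFC perseverer replicate 3, OFC perseverer replicate 2 or OFC renouncer replicate 1, 8 without mPFC renouncer replicate 3 or OFC renouncer replicate 3, 9 without OFC renouncer replicate 2 and 10 without OFC perseverer replicate 3.

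The same difference was compared between the OFC dissections and the imprints, where stage and way of collection cannot be separated. Metabotropic glutamate receptor and scaffold genes had a higher difference after oDASS in 23 of 28 members (median log2 difference 0.73), with 0 members past over all genes or adjusted over the list alone. The list passed (adjusted p = 0.0494; adjusted p = 0.89 with an estimated correlation) and kept its call in 3 of 11 leave-outs. It ended without dissection perseverer replicate 1 (0.0673) or 2 (0.0968), dissection renouncer replicate 2 (0.0561) or 3 (0.0543), imprint perseverer replicate 1 (0.146) or 2 (0.0732), or imprint renouncer replicate 1 (0.425) or 3 (0.0571). The number of lists went from 1 to 0 without OFC dissection perseverer replicate 1, perseverer replicate 2 or renouncer replicate 2 or without imprint perseverer replicate 1 or renouncer replicate 1, to 3 without dissection perseverer replicate 3, to 4 without dissection renouncer replicate 1 or imprint renouncer replicate 3, and to 9 without imprint renouncer replicate 2. Cnnm1, a gene of the metal transporter family CNNM, had the smallest p (3.42 ± 0.61, adjusted p = 0.238), on 8 counts in the 2 perseverer imprints. Of 15229 genes, 0 passed with edgeR (1336 at an unadjusted p under 0.05), 80 with DESeq2 (49 higher, 31 lower) and 0 with limma (737), and 4 passed with edgeR without imprint perseverer replicate 2, where the perseverer imprints are 1 library, assumed to vary like the other groups. On simulated 4-fold changes edgeR recovered 0% here.

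The OFC was then compared with the mPFC across the 12 dissections (6 against 6, with phenotype in the model). Grp, the gastrin-releasing peptide gene on chromosome 18 (65872751 to 65886599), was 6.69-fold lower in the OFC, at 4.54 ± 1.16 CPM against 30.1 ± 8.96 (log2 fold change -2.74 ± 0.20, adjusted p = 2.36e-06). Aldh1a1, a retinoic acid synthesis enzyme on chromosome 19 (20492583 to 20643463), was 5.69-fold higher, at 103.7 ± 20.04 against 18.2 ± 9.81 (2.51 ± 0.29, adjusted p = 3.99e-04). Tmem215, a membrane protein gene on chromosome 4 (40472180 to 40475653), was 4.13-fold higher (2.05 ± 0.20), Scn4b, a sodium channel subunit, 3.48-fold higher (1.80 ± 0.20), and Vamp1, a vesicle fusion protein, 2.43-fold higher (1.28 ± 0.13). All 6 OFC libraries lay beyond all 6 mPFC libraries for each of these 5 genes.

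Other genes higher in the OFC were Kcng4, a potassium channel subunit (2.83-fold), Npnt, the matrix protein nephronectin (1.52 ± 0.19), Plcxd2 (1.05 ± 0.12), Rcan2, a calcineurin regulator (0.83 ± 0.11), Pde8b, a cyclic AMP phosphodiesterase (0.76 ± 0.09), and Cabp1, a calcium-binding protein (0.75 ± 0.10). Lower in the OFC were Nos1, the neuronal nitric oxide synthase (-1.46 ± 0.17), Pcdh19, a protocadherin (-1.24 ± 0.14), Fxyd6, a regulator of the sodium pump (-0.96 ± 0.12), St6galnac5, a sialyltransferase (-0.83 ± 0.10), and Ahi1, a gene of the primary cilium (-0.77 ± 0.09). Lypd1 and Gpr39 overlap on opposite strands and the libraries are not stranded, so that their near-equal values (-1.67 ± 0.10 and -1.67 ± 0.11) cannot be assigned to 1 of them. C1ql3 (-0.83 ± 0.10) shares 61.0% of its exon bases with a predicted gene, and its value is uncertain for the same reason.

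**Figure D4:**
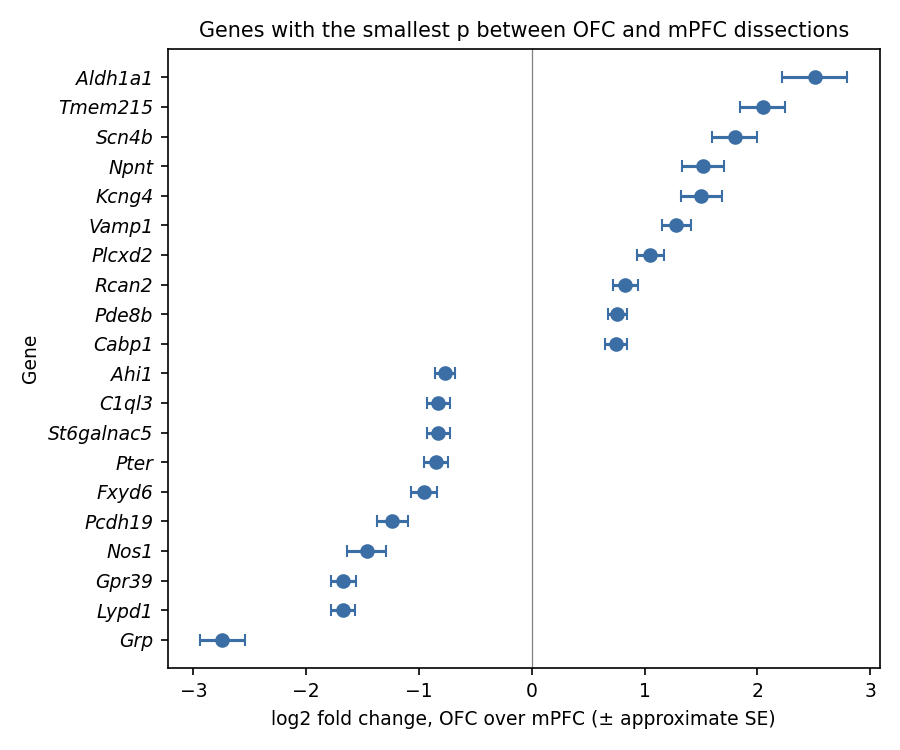
Log2 fold change of OFC over mPFC dissections (horizontal axis) with approximate SE as bars, for the 10 higher and 10 lower genes with the smallest p (6 libraries against 6). Aldh1a1 (2.51) and Grp (-2.74) lie at the ends.

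Of 14409 genes, 266 passed (135 higher and 131 lower in the OFC), 90 of them with a log2 change beyond 1 in size. DESeq2 called 691 and limma 930, with 266 and 263 shared. With the replicate number as a block, which the labels do not say pairs libraries, 1148 passed, with 265 shared. Leaving out 1 library gave 152 without mPFC perseverer replicate 1, 170 without mPFC perseverer replicate 2, 472 without mPFC perseverer replicate 3, 163 without mPFC renouncer replicate 1, 1.2e+02 without mPFC renouncer replicate 2, 121 without OFC perseverer replicate 1, 126 without OFC perseverer replicate 3, 136 without OFC renouncer replicate 2 and 162 without OFC renouncer replicate 3. The libraries of the regions also differed in genes detected. The main fit and the permutations between regions treated all libraries as independent, although equal replicate numbers may pair OFC and mPFC libraries. Thinned to the depth of the smallest library, 16716 ± 144 genes had a count in the OFC and 16080 ± 134 in the mPFC, with each OFC library above each mPFC library (exact permutation p = 0.00216, adjusted p = 0.0202). Without haemoglobin genes, at a lower depth, the numbers were 14465 ± 75.1 and 14250 ± 93.5 (exact permutation p = 0.00433, adjusted p = 0.0242). Their ranges overlapped there (lowest OFC 14374, highest mPFC 14383). At a still lower depth the numbers were 13531 ± 78.5 and 13378 ± 90.2, which did not pass (exact permutation p = 0.0173, adjusted p = 0.0693). Platelet genes lay at a mean log2 level of 1.35 ± 0.07 and 1.17 ± 0.10 (exact permutation p = 0.00216, adjusted p = 0.0202). Other blood measures did not pass, with erythroid genes at 2.04 ± 0.06 in the OFC and 2.09 ± 0.07 in the mPFC (exact permutation p = 0.188). For the haemoglobin share the exact permutation p was 0.836.

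Some glial groups differed between the regions, while microglia markers did not pass (median 0.02, adjusted p = 0.635). Oligodendrocyte and myelin markers lay higher in the OFC in 15 of 15 members (median log2 fold change 0.71), with Mbp, the myelin basic protein, 2.82-fold higher (adjusted p = 0.0528) and Mobp at 1.73 ± 0.44 (0.0606); 0 members passed over all genes and 12 adjusted over the list alone. Astrocyte markers lay higher in 12 of 13 (median 0.29), with Gfap, the intermediate filament of astrocytes, 2.61-fold higher (1.39 ± 0.22, adjusted p = 0.0046) as the 1 member past over all genes and 6 adjusted over the list alone. Interferon-stimulated genes lay higher in 20 of 21 (median 0.55), among them Gbp2 (1.51 ± 0.41), with 0 past over all genes and 1 adjusted over the list alone. Oligodendrocyte precursor markers lay lower in 9 of 11 (median -0.36), among them Cspg4 (-0.75 ± 0.19), with 0 past and 1 adjusted over the list alone. The lists' adjusted p values were 2.56e-10, 9.53e-05, 1.43e-04 and 0.00413 (adjusted p = 0.486, 0.486, 0.634 and 0.486 with an estimated correlation), and all 4 calls were kept in all 12 leave-outs. By library, the mean log2 level of the myelin list was 6.38 ± 0.25 in the OFC and 5.62 ± 0.52 in the mPFC (exact permutation p = 0.0173, adjusted p = 0.0693), and that of the astrocyte list 8.59 ± 0.16 and 8.26 ± 0.10 (exact permutation p = 0.00433, adjusted p = 0.0242). The precursor list stood at 4.34 ± 0.22 and 4.66 ± 0.18 (exact permutation p = 0.0238, adjusted p = 0.0833). Neither the myelin nor the precursor list thus passed by library.

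Immediate early genes and 3 of the receptor and signalling lists lay lower in the OFC, while dopamine signalling (adjusted p = 0.602), metabotropic glutamate (0.363), GABA (0.425) and serotonin and noradrenaline receptor genes (0.575) did not pass. Of 34 immediate early genes, which are induced by neuronal activity, 25 were negative (median -0.26), and 3 fell past the threshold over all genes, namely Nr4a3 (-0.98 ± 0.15), Egr4 (-0.97 ± 0.20) and Nptx2 (-0.82 ± 0.18), with 2 higher and 11 lower adjusted over the list alone. Opioid, endocannabinoid and neuropeptide genes were negative in 24 of 33 (median -0.32), with 0 past over all genes and 4 higher and 10 lower adjusted over the list alone, such as Tac2 (-0.60 ± 0.15) and Cckbr, a cholecystokinin receptor (-0.58 ± 0.15). Ionotropic glutamate receptor genes were negative in 11 of 18 (median -0.19), with Gria1, an AMPA receptor subunit (-0.50 ± 0.09), past over all genes and 3 adjusted over the list alone. Neurotrophin and growth factor genes were negative in 14 of 22 (median -0.20), with Mapk3, a kinase downstream of growth factors (-0.79 ± 0.14), and Gfra2, a neurturin receptor (-0.45 ± 0.10), past over all genes and 1 higher and 5 lower adjusted over the list alone. The adjusted p values were 2.68e-05, 0.0017, 0.0228 and 0.0293 (adjusted p = 0.54, 0.486, 0.486 and 0.486 with an estimated correlation). The ionotropic list ended without OFC perseverer replicate 3 (0.0737) or OFC renouncer replicate 2 (0.0631), and the growth factor list without mPFC perseverer replicate 1 (0.0567), OFC perseverer replicate 3 (0.0651) or OFC renouncer replicate 3 (0.0672).

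The last comparison set the 5 OFC imprints against the 6 OFC dissections. Imprints were taken before and dissections after oDASS, so that it contrasts the 2 kinds of library and not the effect of oDASS. Genes of platelets and other blood cells were higher in the imprints. Ctla2a, on chromosome 13 (60934155 to 60936625), was 597-fold higher (log2 fold change 9.22 ± 0.38, adjusted p = 5.2e-10), Gp9, a platelet membrane glycoprotein, 602-fold (9.23 ± 0.45), Pf4, the platelet factor of alpha granules, 984-fold (9.94 ± 0.50), Rgs18, a regulator of platelet signalling, 456-fold (8.83 ± 0.44), Srgn, a granule proteoglycan, 61.4-fold (5.94 ± 0.29), and Cnn2, a calponin, 101-fold (6.66 ± 0.32). Ctla2b is a close paralog of Ctla2a and overlaps a predicted gene, so reads of both are not surely assigned.

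Neuronal genes were lower in the imprints relative to all genes. Stk32c, a kinase gene of the brain on chromosome 7 (139103638 to 139213307), was 12.8-fold lower (-3.68 ± 0.27, adjusted p = 5.26e-08), Serpini1, the neuronal protease inhibitor neuroserpin, 10.4-fold (-3.38 ± 0.25), Penk, the enkephalin precursor, 17.2-fold (-4.11 ± 0.54), Vip 10.2-fold (-3.35 ± 0.41), Snap25, a vesicle fusion protein of nerve terminals, 4.78-fold (-2.26 ± 0.27), Gad1, the GABA synthesis enzyme, 3.04-fold (-1.60 ± 0.30), and Slc17a7 2.15-fold (-1.10 ± 0.23). Of 14236 genes, 4708 passed (2216 higher and 2492 lower in the imprints), and 3869 had a log2 change beyond 1 in size. The balance of directions depended on the processing. RLE scaling called 2453 genes higher and 2151 lower, and removal of the length trend 3299 higher and 1525 lower. Scaling by library totals alone moved the median fold change by -2.71 and called 221 genes higher and 9852 lower, and 1455 of the 2216 higher genes had a change smaller than that shift. Within renouncers alone, a set with the imprint of 29.7% haemoglobin, 1778 genes passed, and within perseverers alone 3867.

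By group, blood cell markers rose in 9 of 9 members and infiltrating immune markers in 12 of 14. Interferon-stimulated genes rose in 17 of 21, such as Isg15 (8.74 ± 0.99), microglia markers in 11 of 14 and inflammatory genes in 12 of 18, with 2 lower, and ribosomal protein genes in 29 of 78, with 1 lower. P2ry12, a purine receptor gene of the microglia list (2.08 ± 0.19), Ctss (1.42 ± 0.23), Tmem119 (1.47 ± 0.31) and Rplp0, a ribosomal protein gene (2.55 ± 0.38), turned lower under library totals. Blood cells also express some genes of the microglia list. Per library total, its mean log2 level was lower in the imprints, at 3.75 ± 1.38 against 6.13 ± 0.21 (exact permutation p = 0.00866, adjusted p = 0.0105). Adjusted over the list alone, 9, 12, 17, 11, 13 and 31 members were higher. The adjusted p values were 1.18e-20, 1.46e-21, 3.35e-08, 1.23e-04, 1.23e-04 and 6.45e-05 (adjusted p = 0.0828, 0.0828, 0.183, 0.359, 0.183 and 0.617 with an estimated correlation).

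Among the lower groups, opioid, endocannabinoid and neuropeptide genes fell in 27 of 32 members, GABA receptor genes in 11 of 15, inhibitory neuron markers in 11 of 14, pan-neuronal genes in 9 of 13, excitatory neuron markers in 9 of 12 with 1 higher, synaptic vesicle genes in 18 of 33 and voltage-gated potassium channels in 14 of 25. Cnr1, the cannabinoid receptor of nerve terminals, stood at -2.32 ± 0.30 and Sv2b, a synaptic vesicle protein, at -3.08 ± 0.38. Adjusted over the list alone, 27, 11, 11, 9, 9, 19 and 17 members were lower, and the adjusted p values ran from 7.14e-08 for the neuropeptide list to 5.7e-04 for the excitatory list (adjusted p = 0.183 with an estimated correlation for each of the 7). Dopamine signalling genes fell in 9 of 21 (10 adjusted over the list alone), among them the receptor gene Drd1 (-3.13 ± 0.63, on 19 counts in the imprints), deep-layer markers in 9 of 15 (9 alone), metabotropic glutamate receptor and scaffold genes in 11 of 28 with 1 higher (11 lower alone) and striatal markers in 5 of 12 with 1 higher (5 alone). Their adjusted p values were 0.0197, 0.0135, 0.0135 and 0.0259 (adjusted p = 0.211, 0.384, 0.56 and 0.183 with an estimated correlation), and all 17 lists kept their calls in each of the 11 leave-outs.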

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

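The tests of gene length on the lists, of the mPFC lists without perseverer replicate 3, of blood lineages, of haemoglobin copies and of microglia and precursor levels were chosen after the result was seen. Of 48 groups examined for a library far from the others (16 overlapping measures in tables of 5, 6 and 6 libraries), 12 held one, 9 times the same library, where chance gives about 1 in 20.

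Imprint renouncer replicate 1 stood far from the other 4 imprints in 9 measures. Its haemoglobin share was 29.7% (nearest other 85.4%), the share of its 50 most abundant genes 43.1% (89.8%), and its genes with a count 16479 (13369). Its mean log2 CPM were 5.62 for excitatory neuron markers (nearest other 2.97), 4.82 for endothelial markers (1.33), 3.92 for meningeal fibroblast markers (1.28), 1.18 for choroid plexus markers (0.359), 2.51 for striatal markers (0.714) and 1.62 for neuroblast markers (0.577).

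In the mPFC dissections, perseverer replicate 3 stood apart in the share of its 50 most abundant genes, at 13.1% (nearest other 11.8%), and in neuroblast markers, at a mean log2 level of 2.71 (2.07). Renouncer replicate 1 of the mPFC had 16624 genes with a count (nearest other 16336).

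By a test of the difference itself at a preset correlation, the difference between phenotypes differed between regions for endothelial markers (median 0.45), meningeal fibroblast markers (-0.83) and neuroblast markers (-0.73), with adjusted p = 0.626, 0.968 and 0.626 with an estimated correlation. The meningeal and neuroblast calls each ended in 3 of 12 leave-outs: without mPFC perseverer replicate 3 (0.186 and 0.286), mPFC renouncer replicate 2 (0.081 and 0.0792), and OFC renouncer replicate 2 (0.538, meningeal) or OFC renouncer replicate 3 (0.076, neuroblast). Between stages the test passed for metabotropic glutamate receptor and scaffold genes (0.73, adjusted p = 0.0494), with adjusted p = 0.89 with an estimated correlation, and the call was kept in 3 of 11 leave-outs.

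Gene lists passed between perseverers and renouncers after oDASS at a preset correlation, and 0 passed with an estimated one (smallest adjusted p 0.799 in the OFC and 0.506 in the mPFC). Gene length is a candidate explanation for oxidative phosphorylation and ribosomal genes: with each library's length trend removed, 2 of 2 lists in the OFC and 2 of 2 in the mPFC lost their call and most of their fold, oxidative phosphorylation genes from a median of -0.25 ± 0.14 (SD over members) to -0.02 ± 0.13 and from -0.19 ± 0.12 to -0.01 ± 0.11, ribosomal genes from -0.20 ± 0.15 to -0.02 ± 0.15 and from -0.11 ± 0.17 to 0.06 ± 0.18. The removal also takes out any change that genes of like length share for another reason, so that it does not single out length. The other lists that lost their call kept 0.577 to 0.974 of their median in the OFC and 0.328 to 0.776 in the mPFC, with 0 of 5 and 1 of 8 below 0.5, so that length and phenotype cannot be told apart for them: in the OFC glutamate scaffold genes (0.17 ± 0.22 to 0.16 ± 0.23), astrocyte (0.13 ± 0.14 to 0.12 ± 0.12), meningeal (-0.33 ± 0.44 to -0.27 ± 0.44), clock (0.22 ± 0.18 to 0.14 ± 0.16) and upper-layer genes (0.22 ± 0.19 to 0.12 ± 0.19), in the mPFC potassium channels (0.19 ± 0.21 to 0.06 ± 0.23), growth factor genes (0.26 ± 0.30 to 0.13 ± 0.30), inhibitory markers (-0.16 ± 0.24 to -0.08 ± 0.20), sodium and calcium channels (0.22 ± 0.25 to 0.12 ± 0.27), clock (0.19 ± 0.23 to 0.13 ± 0.24), vesicle (0.13 ± 0.23 to 0.09 ± 0.22), spine (0.17 ± 0.26 to 0.12 ± 0.21) and glutamate scaffold genes (0.16 ± 0.30 to 0.13 ± 0.28). Length as the whole source of the call at the preset correlation is argued against for OFC endothelial markers (adjusted p = 0.00625 after removal). The same holds for mPFC neuroblast and meningeal markers (2 of 2 kept). Before removal none of these calls passed with an estimated correlation, and all 10 OFC splits gave at least as many lists as phenotype. A difference between phenotypes beyond chance was therefore not shown for them. The neuroblast and meningeal calls also ended without mPFC perseverer replicate 3 (0.277 and 0.938), and 0 of the 12 mPFC lists kept their call in both checks. That library alone is argued against as the source of all mPFC lists (6 of 12 stay without it) and of the mPFC length trend (0.464 without it), while phenotype, RNA quality and a processing order behind the sample code numbers, which did not mark the highest split in the mPFC, stay open, since the labels name no batch.

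Genes differed between the OFC and the mPFC, and more myelin in the OFC libraries was weighed against a difference of the regions themselves. With the myelin level as a covariate, the median ratio of the fold changes after and before was 0.85 and 266 of 266 genes kept their sign, which argues against myelin as the whole cause. Only 41 genes passed in that fit, 30 of them shared, as the median size of the log2 fold change went from 0.83 to 0.64 and the median SE from 0.15 to 0.20. Removal of the length trend tested nothing here, since the fold changes hardly followed gene length before it (Spearman correlation -0.0578). A difference of the regions stays open as a hypothesis, as do dissection borders and a difference between the libraries themselves, both untested. Thinned to the depth of the smallest library, each OFC library detected more genes than each mPFC library (16716 ± 144 against 16080 ± 134). Without haemoglobin genes, at a lower depth, the libraries overlapped (lowest OFC 14374, highest mPFC 14383).

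Blood genes filled the imprints, and blood carried on the imprint may account for them. All 4 blood lineages had a higher mean log2 level in each imprint than in each OFC dissection: erythroid genes (lowest imprint 5.65, highest dissection 2.10), platelet genes (3.73, 1.48), lymphocyte genes (2.25, 0.284) and neutrophil genes (1.30, 0.698). Reads counted at several haemoglobin copies are argued against as the whole source of the share in the 4 most blood-rich imprints. The lowest share among these was 74.5% with each near-identical pair counted once. In renouncer replicate 1 the share was 17.5% counted so, against 29.7%, so that repeated counting may add a part. Even dilution of all brain RNA by blood cannot be told apart from uneven loss for the marker lists that follow. Oligodendrocyte precursor markers had a lower quartile above the upper quartile of the pan-neuronal list in 3 of 5 imprints (2.97 to 5.48 times its median). These 3 rest on low median counts of 10.5 to 21.5. The other 2 imprints lay within 2 times, among them renouncer replicate 1 (1.44 times), where the list had its highest median count. Microglia markers lay above in 5 of 5 (2.04 to 7.37 times), but blood cells also express some of these genes. For excitatory, inhibitory, astrocyte and myelin markers, neuronal counts were few. At most 2 imprints had 1 of these lists more than 2 times from the pan-neuronal level on the same side. Stage and way of collection coincide, so that an effect of stage was not tested.

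Other splits of the libraries were counted beside each result. In the OFC dissections, 3 against 3 libraries give 10 splits, too few for a share under 0.05. Of these, 6 gave as many genes at an unadjusted p under 0.05 as the real 377 (highest other 3064). All 10 gave at least as many lists as the real 8 (highest other 16), so that phenotype gave no more lists than any other split. In the mPFC, also with too few splits, 5 gave as many genes as the real 639 (highest other 2309) and 4 as many lists as the real 12 (highest other 13). The highest OFC split set renouncer replicate 1 and perseverer replicates 1 and 2, which hold the lower sample code numbers, against the rest and called 582 genes, which points to a structure of the samples other than phenotype. These libraries also had the highest gene length trends, at 0.289, 0.251 and 0.374. In renouncer replicates 2 and 3 and perseverer replicate 3 the trends were -0.360, -0.420 and -5.1e-04. In the mPFC the split by code numbers called 0 genes with edgeR (1084 at an unadjusted p under 0.05, against 639 for the real split), and the highest set renouncer replicates 1 and 3 and perseverer replicate 3 against the rest. With the code numbers as a covariate, the OFC kept 0 genes past the threshold with edgeR (935 at an unadjusted p under 0.05).

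For the regional genes, 3 of 100 splits, the real one included, gave as many as the real 266, a share under 0.05. The highest other gave 1729, several times the real count, so that a count of that size also arises from another grouping. Chance is therefore not excluded by the share alone. The high count again points to a structure of the samples, and the splits treated all libraries as unpaired. For the regional lists chance was not excluded (51 of 100; real 8, highest other 17), nor for the interaction with region, in genes at an unadjusted p under 0.05 (100 of 100; real 225, highest other 4329) or in lists (95 of 100; real 3, highest other 19). For imprint against dissection, 1 of 100 splits, the real one, gave 4708 genes (highest other 1429), which excludes chance, while 29 of 100 gave as many lists (real 17, highest other 24), which does not.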

How the results depend on the processing

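Removal of the length trend, library totals alone, the myelin and sample code covariates, removal of haemoglobin genes or copies, and for lists the stricter filter, no filter and the fit of all 17 libraries were chosen after seeing the data. Of 1107 values for 82 named genes past the threshold, 1012 kept direction and side of the threshold, 91 lost their call and 4 reversed; of 607 values for 50 called lists, 453 kept both, 149 lost the call and 5 reversed. For changed results the cause was not tested, except that fits within 1 phenotype hold fewer libraries. An estimated correlation gave 0 lists in each of the 7 comparisons, and fry 0 in each but imprint against dissection (28). Imprint phenotype lists numbered 2 without a filter, with the replicate number as a block or under library totals and 0 in the fit of all 17 libraries, which called 63 genes. The fit of all 17 libraries gave 4 lists in the OFC and 7 in the mPFC, removal of the length trend 3 and 2, and the sample code covariate 4 in the mPFC. Regional genes numbered 538 at a threshold of 0.1, 691 with DESeq2, 930 with limma, 1148 with the replicate block, 15 in renouncers alone, 8 in perseverers alone and 41 with the myelin covariate. Imprint against dissection gave 1778 genes in renouncers alone and 10073 under library totals. The interaction with stage gave 80 genes with DESeq2, and 0 lists with the stricter filter or without the length trend, 6 with the replicate block and 3 under library totals. The labels do not say whether replicate numbers pair libraries: between regions 5 of 6 equal numbers correlated at 0.206 to 0.629 and 1 at -0.0524, and 8 of 12 dissections correlated best with their own number (4 expected without pairing, with 3 candidates each), which with adjacent sample codes is a hint of pairing from the data.

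Reversed values were the adjusted p of ribosomal protein genes without the length trend (OFC 0.965, mPFC 0.344), with the sample code covariate (0.254, 0.632) and without OFC renouncer replicate 3 (0.629), mPFC perseverer replicate 2 (0.795) or mPFC renouncer replicate 3 (0.265), of the myelin list with the myelin covariate (0.744), and of OFC meningeal markers without renouncer replicate 2 (0.141). Log2 fold changes reversed for Mgp without OFC renouncer replicate 2 (0.23), for Doc2g without mPFC perseverer replicate 3 (-0.41; interaction 0.64), and under library totals for Ctss (-1.61), P2ry12 (-0.72), Rplp0 (-1.18) and Tmem119 (-1.963).

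With each library left out in turn, lists ran from 0 to 6 in the imprints, 8 to 11 in the OFC, 4 to 14 in the mPFC, 7 to 11 between regions, 2 to 10 for the interaction with region, 17 to 21 between imprint and dissection and 0 to 9 for the interaction with stage. Genes ran from 1.2e+02 to 472 between regions, 3719 to 5309 between imprint and dissection and 0 to 4 for the interaction with stage, and stayed at 0 with edgeR in the other 4 comparisons (181, 377, 639 and 225 at an unadjusted p under 0.05; DESeq2 and limma 0). The concordance of imprint and OFC dissection ran from -0.0838 to 0.0303, reversed without imprint renouncer replicate 1 (0.0303) or perseverer replicate 1 (0.0103), and that of OFC and mPFC from 0.178 to 0.278; relabelling equal replicate numbers of both regions together gave it a permutation p of 0.3 over 20 relabellings. The phenotype difference in length trend ran from -0.181 to 0.218 in the imprints (reversed without renouncer replicate 1, 0.218, or perseverer replicate 1, 0.0255, which leaves 1 perseverer), 0.244 to 0.598 in the OFC and 0.339 to 0.550 in the mPFC. For results with a reversal, the adjusted p ran from 2.46e-18 to 0.629 for OFC ribosomal genes, 4.01e-10 to 0.795 for mPFC ribosomal genes and 3.05e-10 to 0.402 for OFC meningeal markers, and the log2 fold change from -1.62 to 0.23 for Mgp, from -0.41 to 2.66 for Doc2g in the mPFC and from -2.48 to 0.64 for its interaction. The haemoglobin difference ran from 73.7 to 88.9 percentage points, and that of the regions in genes detected from 594 to 682, or 193 to 241 without haemoglobin genes.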

Other observations

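No test in this part was chosen after the result was seen except the removal of the length trend. Some regional genes belong to lists that were not called as a whole. Ppp1r1b, a dopamine-regulated phosphatase inhibitor, was higher in the OFC (log2 fold change 0.76 ± 0.12, adjusted p = 0.00474), as were Cux1, a cortical transcription factor (0.61 ± 0.11, 0.0125), and Rora, a clock-related nuclear receptor (0.55 ± 0.13, 0.0403). Rgs2, a regulator of G protein signalling (-0.60 ± 0.10, 0.00484), and Syn2, a synaptic vesicle protein (-0.64 ± 0.13, 0.0203), were lower in the OFC (6 libraries against 6).

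Immediate early genes did not pass between perseverers and renouncers, with 18 of 34 positive in the OFC (adjusted p = 0.708), 16 of 34 in the mPFC (0.929) and 9 of 21 in the imprints (0.385). Dopamine receptor and signalling genes were positive in 11 of 21 in the OFC (0.41), 12 of 21 in the mPFC (0.697) and 6 of 13 in the imprints (0.797). In these lists 0 members passed over all genes.

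A trend with gene length shared by both regions may raise the correlation of their phenotype fold changes. With the trend of each library removed the Pearson correlation was 0.209, against 0.269 before. Neither passed against relabelled libraries (permutation p = 0.2 and 0.13; highest other 0.455 before removal), so that a correlation beyond chance was not shown and the test decides nothing on its source.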
